A study of Mus musculus with 55 samples.

How the data were processed

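Messenger RNA was sequenced from the white fat beside the gonads of 6-month-old C57BL/6 mice, in 55 libraries with 1 library per animal. The animals were wild type or heterozygous for a knock-in Htt allele whose name gives its CAG repeat length (Q20, Q80, Q92, Q111, Q140 and Q175), of both sexes. The 14 groups of genotype and sex held 4 libraries each, except that wild-type females had 3. Per the labels, RNA was extracted from frozen tissue with the Qiagen miRNeasy kit, its integrity was followed on an Agilent Bioanalyzer, and an enriched RNA fraction went into Illumina libraries. The submitters' processing notes name CASAVA 1.8.2. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

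The authors deposited a table of estimated read counts (expected counts, not scaled) and a table of FPKM values, scaled by the authors for gene length and sequencing depth, each with 43432 Ensembl genes in 55 columns. Of the nonzero counts, 33.7% were not whole numbers, and all counts were rounded before use. Every value column was matched to a library through the label that repeats its name. Symbols, transcript lengths and gene types came from GENCODE M21, which held 42462 of the 43432 identifiers. A count above 0 was found for 32566 genes. The total count per library lay between 35094400 and 51363600 with a median of 42009400. Reads carried no molecular identifiers, so depth bounds the counting error only and the error between animals is given as an SD.

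Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter over the 14 groups (21113 genes kept) and a robust quasi-likelihood fit of 1 mean per group. Genotype comparisons are the mean of the female and the male difference. The trend over CAG length is the slope of the group means on the repeat number over the 6 knock-in genotypes, in log2 units per 100 repeats, also taken in each sex and as the difference between the sexes. The male to female difference is the mean over the 7 genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Levels are CPM on TMM-scaled library sizes, as mean ± SD over libraries, and log2 fold changes are given ± their standard error (SE). Unless another tool is named, adjusted p values are from edgeR.

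The lists of genes, the rule for naming genes and the alternatives were set before the data were examined, except where stated. The lists were adipocyte identity, lipogenesis and triglyceride synthesis, cholesterol biosynthesis, fatty acid oxidation, brown and beige thermogenesis, oxidative phosphorylation, insulin signalling, extracellular matrix, interferon response, heat shock response, unfolded protein response, circadian clock, immediate early genes, cell cycle, genes beside Htt, and markers of macrophages, lymphocytes, progenitors, endothelium, mesothelium, epididymis and testis, the female tract (ovary, oviduct and uterus), mammary epithelium, skeletal muscle, erythroid cells, Schwann cells and exocrine pancreas. For each list the members called over all genes were counted, and also those called when p was adjusted over the list alone. Lists were tested with limma 3.58.1 on voom values: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Each was adjusted over the lists of a comparison. The lists were fixed for the Q175, Q140, Q20 to WT, trend and sex comparisons. Their use on Q92 was added after the counts for Q92 had been seen. Fbn1 belongs to both the extracellular matrix and the progenitor list.

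Genes were named by rule: per comparison the 12 raised and 12 lowered genes with the smallest p among those called, leaving out symbols of predicted genes, up to 4 members of each list with the smallest p, Htt, and Xist, Ddx3y, Kdm5d, Eif2s3y, Uty and Nnt as library checks. The alternatives were RLE and upper-quartile scaling, no low-count filter or a mean of 1 CPM, DESeq2 1.42.0, limma voom with quality weights, limma-trend on log2 FPKM with 0.1 or 1 added, no robust step, an additive design, the replicate number as a block, the lane code as a factor, 3 surrogate variables (sva 3.50.0), only the genotypes compared, other ranges or ranks of CAG length for the trend, a threshold of 0.01, and leaving out each library in turn. Alternatives chosen after seeing the data were exchanging or leaving out the 2 Q140 libraries whose sex genes contradict their labels, leaving out libraries with at least 100 CPM of the epididymis and testis markers, the female libraries alone, removing each library's trend over transcript length, and leaving out genes of small and ribosomal RNAs. Leaving out the libraries high in epididymis and testis markers also left out these 2 Q140 libraries and used an additive design of sex and genotype. The female libraries alone were taken without Q140 female 1. Lars2 was left out together with the small and ribosomal RNAs. In the library names the same lane code, with the same code after it, recurs in both blocks, as in Q20 male 4 and Q175 male 3. A lane code therefore need not stand for 1 lane, and the setting with the lane code need not adjust for lane. The pipeline was tested on simulated counts drawn from a negative binomial, with 1 mean and 1 dispersion per gene and the library sizes of the real data. Known folds were given to known genes for the Q175, Q92, Q140 and trend comparisons. These counts held no sex difference, block, lane or foreign tissue. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the reported values.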

Results

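Gonadal white fat, which lies beside the epididymis in males and beside the ovary and uterus in females, was measured in mice with an inserted CAG repeat in 1 copy of Htt, the gene mutated in Huntington's disease. The repeat length named by each line was 20, 80, 92, 111, 140 or 175 repeats. Wild-type (WT) mice and the Q20 line, whose repeat is in the unexpanded range, were the controls. WT and Q20 animals were housed together and each other genotype with its own, so housing cannot be told apart from genotype. The library numbers form 2 blocks, with all 15 WT and Q175 libraries in 1 and 39 of the other 40 in another. So Q175 against Q20 and Q20 against WT also compare blocks, and the slopes over CAG length set Q175 in 1 block against the other lines in the other. Q175 against WT lies within 1 block. There were 7 WT libraries and 8 of every other genotype.

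Xist, the RNA that silences the second X chromosome, had 651 ± 199 CPM in female libraries and 27.3 ± 134 CPM in male ones. The Y-linked RNA helicase gene Ddx3y had 2.88 ± 14.7 CPM in females and 59.2 ± 22.5 CPM in males. In 2 Q140 libraries these genes contradicted the labels: female replicate 1 had Xist at 0.515 CPM and Ddx3y at 76.6 CPM, and male replicate 4 had Xist at 711.8 CPM. Nnt, which is partly deleted in the C57BL/6J substrain, had 25.0 CPM in WT, 25.2 CPM in Q20 and 29.8 CPM in Q140, and was called in no comparison of genotypes. Markers of the epididymis and testis summed to at least 100 CPM in 15 male libraries, among them all 4 of Q175 and none of WT.

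**Figure D1:**
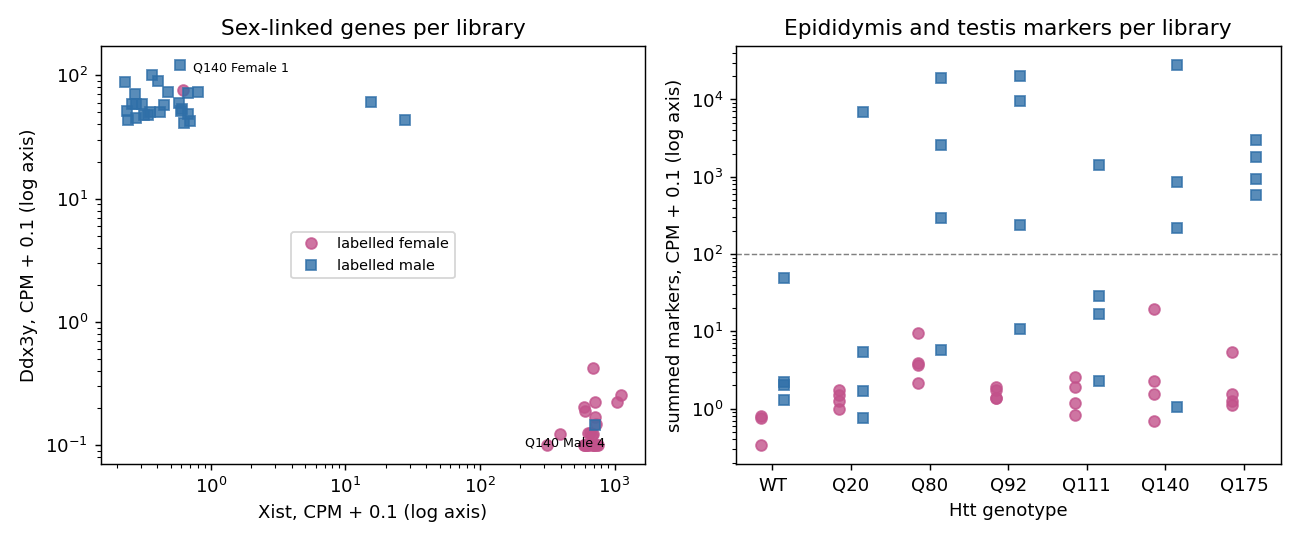
Left, Xist against Ddx3y in CPM on log axes in each library by labelled sex, with the 2 Q140 libraries (Xist 0.515 and 711.8 CPM) on the side of the other sex. Right, summed epididymis and testis markers in CPM on a log axis by genotype, with 15 male libraries above the dashed line at 100 CPM.

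Htt itself (ENSMUSG00000029104), which encodes the large scaffold protein huntingtin, had 66.1 ± 9.07 CPM in WT, 58.5 ± 5.07 in Q20, 53.3 ± 3.13 in Q80, 49.4 ± 5.46 in Q92, 47.9 ± 6.43 in Q111, 45.5 ± 5.03 in Q140 and 57.4 ± 2.74 in Q175. Among the comparisons of genotypes edgeR called it only in Q92 against Q20, at log2 -0.25 ± 0.07 (adjusted p = 0.0275), and that call ended without any 1 of 6 libraries. DESeq2 called it in Q111 (-0.29) and Q140 (-0.35), voom with quality weights in Q111 (-0.30) and in Q175 against WT (-0.17), and the additive design in Q140 (-0.37), and with the length trend removed it was called in Q175 against WT (-0.38). The values against Q20 were -0.13 in Q80, -0.29 in Q111, -0.36 in Q140 and -0.03 in Q175, with adjusted p from 0.164 to 0.886. The falls in Q111 and Q140 (SE 0.07 in each) were larger than in Q92, and their unadjusted p were smaller. In Q140 no gene had a smaller adjusted p than Htt. The adjustment depends on the other genes of a comparison, and 1291 were called in Q92 against 0 in Q111 and Q140. The call in Q92 therefore does not mark it as the line with the best-supported fall. Q20 stood at -0.18 to WT (adjusted p = 0.352) and Q175 at -0.21 to WT (adjusted p = 0.0665). The slope over all 6 lines was -0.09 ± 0.04 per 100 repeats (adjusted p = 0.221). It turned positive on FPKM with 0.1 added (0.063) and over Q80 to Q175 (0.10), and was called with the length trend removed (-0.18). When the slope was taken over Q20 to Q140 alone, it was -0.32 ± 0.06 per 100 repeats (adjusted p = 0.0316), and Htt was the only gene called. That call ended with RLE scaling (adjusted p = 0.0559), without the 2 Q140 libraries above (adjusted p = 0.0824) and in the female libraries alone (-0.41, adjusted p = 0.183). In the fit of all libraries it was -0.42 in the female groups (adjusted p = 0.0328) and -0.21 in the male groups (adjusted p = 0.81). On FPKM with 0.1 added, the slope over Q20 to Q140 was -0.22 (adjusted p = 0.90), and the values for Q175 turned positive, at 0.24 to Q20 and 0.02 to WT.

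**Figure D2:**
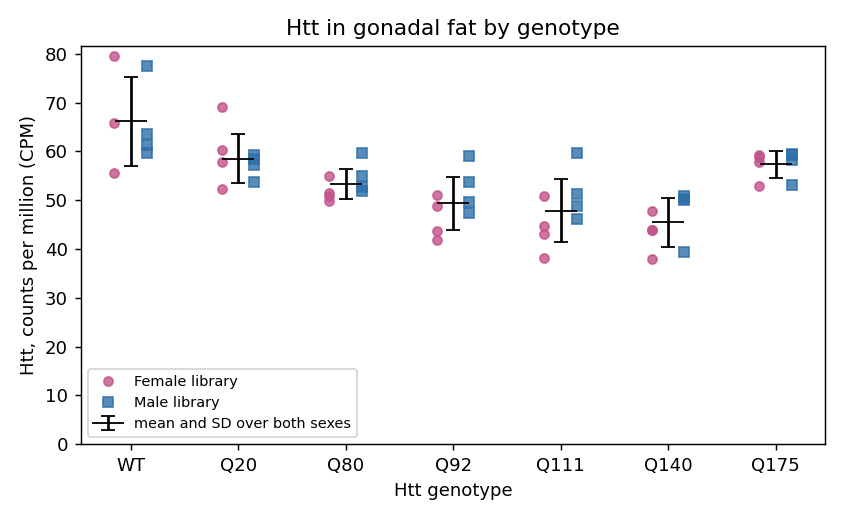
Htt in CPM in each library by genotype and sex, with genotype means. The means ran from 66.1 CPM in WT to 45.5 CPM in Q140, and Q175 had 57.4 CPM.

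In Q175 against WT, 2204 of 21113 genes were called, of which 1498 were lower. On FPKM with 0.1 added the median of all tested genes moved to 0.17. The balance there turned to 2027 higher and 334 lower, with 66 of the 2204 at the opposite sign. It was 1217 and 1200 in an additive design without the libraries high in epididymis and testis markers, where design and libraries changed together. Sema3d, a secreted guidance factor of the semaphorin family, rose by log2 1.95 ± 0.30 (adjusted p = 0.000255; 7.34 ± 0.909 against 1.93 ± 1.41 CPM). Reck, which restrains matrix metalloproteinases, rose by 0.93 ± 0.15 (21.1 against 10.9 CPM), the transcription factor Etv1 by 1.44 ± 0.25 (6.85 against 2.50 CPM) and the lipid transporter Abca9 by 1.12 ± 0.20 (54.1 against 25.4 CPM). The myeloid receptor Cd33 rose by 1.11 ± 0.20, Sema3e by 1.57, the scavenger receptor Scara3 by 1.03 and Qpct, which cyclizes glutamine at peptide ends, by 1.15. Pcdhgc4, a protocadherin of the gamma cluster, fell by 3.03 ± 0.41 (adjusted p = 4.75e-05), with 7.77 ± 6.57 CPM in Q175, 61.4 ± 31.0 in WT and 35.8 in Q20. Uqcrh of respiratory complex III fell by 0.82 ± 0.14 (137 ± 17.7 against 238 ± 49.9 CPM), Mrpl11 of the mitochondrial ribosome by 0.64 ± 0.10, the mitochondrial protease Parl by 0.55 ± 0.09, the cochaperone Dnajc7 by 0.42 ± 0.06 and the poly(A)-binding Pabpn1 by 0.55.

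Of the 60 oxidative phosphorylation genes, 48 fell in Q175 against WT and none rose, and 57 fell when adjusted over the list alone. Their median was -0.56, and Ndufa2 (-0.75) and Ndufa3 (-0.70) of complex I and Cox7c (-0.73) of complex IV were among them. On FPKM with 0.1 added 34 fell and none rose. The camera call was lost with a correlation taken from the data (adjusted p = 0.398 with an estimated correlation; fry adjusted p = 0.00266). Reads of mitochondrial genes, not tested, made up 7.61 ± 1.07% of counts in Q175 and 11.3 ± 2.23% in WT. Of the progenitor markers, 5 of 12 rose and 6 when adjusted over the list alone: the microfibril gene Fbn1 by 1.44, Pi16 by 1.32, Dpp4 by 1.20 and the growth factor receptor Pdgfra by 0.83 (adjusted p = 0.0800 with an estimated correlation; fry adjusted p = 6.36e-05). Of the macrophage markers, 5 of 19 rose (6 over the list alone), with Cd163 at 1.11, Adgre1 at 0.96, Mrc1 at 0.91 and Csf1r at 0.83. Of the matrix genes 4 of 24 rose (9 over the list alone), with Fn1 at 1.68, Bgn at 0.77 and Dcn at 0.58 beside Fbn1. Both lists had adjusted p = 0.864 with an estimated correlation and fry adjusted p = 0.0815. Among single members, the stress regulator Atf4 fell by 0.61, the chaperone Hspe1 by 0.48, Ebp of cholesterol synthesis by 0.38, and Msantd1 and Haus3 beside Htt by 1.20 and 0.64. Cpt1a of fatty acid oxidation rose by 0.52. The epididymal genes Crisp1 (8.94) and Gpx5 (8.35) and the keratin Krt5 (8.91) rose, and the epididymis and testis markers summed to 584 to 2993 CPM in the Q175 males. Over the other settings and left-out libraries the call was lost in 22 of 36 for Hspe1, 19 of 36 for Dcn, 18 of 36 for Haus3 and 17 of 34 for Gpx5.

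Genes called higher in Q175 against WT had a median transcript length of 2281 nt and those called lower 862 nt. In the female libraries alone 1322 genes were called, where 39 oxidative phosphorylation genes fell (59 over the list alone), 6 progenitor markers (6 also over the list alone) and 9 macrophage markers (13 over the list alone) rose, and 4 lipogenesis genes fell (13 over the list alone). These camera calls were lost at adjusted p = 0.422, 0.144, 0.422 and 0.666 with an estimated correlation, and lipogenesis also missed the threshold by fry (adjusted p = 0.102). The count fell to 1101 without WT female 1, 1073 without WT female 3, 1382 without WT male 3, 1299 without Q175 male 3 and 1367 without Q175 male 4. It was 417 with the lane code as a factor, 1434 without the low-count filter, 8416 by voom with quality weights, 6002 on the libraries of these genotypes alone and 808 at a threshold of 0.01.

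**Figure D3:**
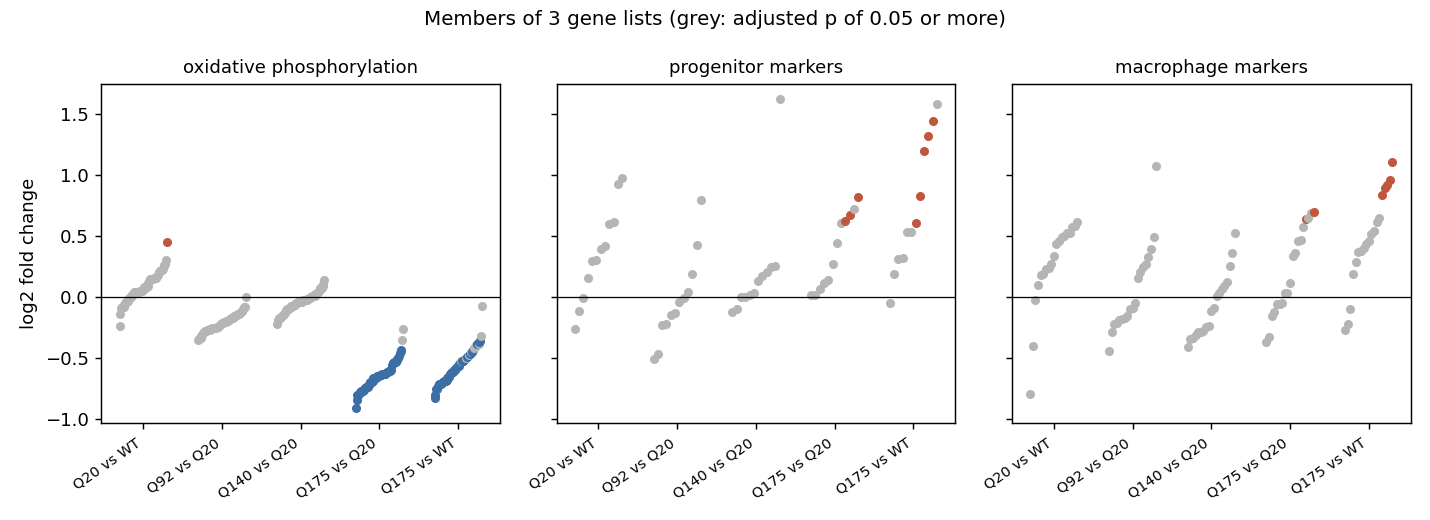
Log2 fold change of each member of the oxidative phosphorylation, progenitor and macrophage lists in 5 comparisons, with members at adjusted p of 0.05 or more in grey. In Q175 against WT 48 of 60 oxidative phosphorylation genes fell, and 5 of 12 progenitor and 5 of 19 macrophage markers rose.

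Q175 against Q20 gave 3006 calls, 958 higher and 2048 lower. On FPKM with 0.1 added, where the median of all tested genes moved to 0.20, 3235 were higher and 577 lower, with 167 of the 3006 at the opposite sign. The autophagy scaffold Wdfy3 rose by 0.62 ± 0.08 (adjusted p = 3.34e-06; 93.9 ± 9.42 against 61.2 ± 4.35 CPM), the histone methyltransferase Kmt2a by 0.64 ± 0.09 (97.1 against 62.2 CPM), the ubiquitin ligase Herc2 by 0.52 ± 0.07, the RNA silencing gene Ago2 by 0.51 ± 0.07 and the kinase Wnk1 by 0.37 ± 0.06. Pfdn1, a subunit of the chaperone prefoldin, fell by 0.56 ± 0.07 (adjusted p = 3.29e-07; 22.9 ± 1.64 against 33.8 ± 2.81 CPM), and the splicing factor Bud31 by 0.64 ± 0.08. Small structural RNAs fell far, as Rn7s1 of the signal recognition particle by 7.73 ± 0.82 and the transcription regulator Rn7sk by 5.94 ± 0.66. With them Lars2, annotated as the mitochondrial leucyl-tRNA synthetase gene, fell by 4.40 ± 0.54. It was left out with the small and ribosomal RNAs in that setting, and followed the predicted gene Gm42418 across libraries. Lars2 and Gm42418 had 11678 and 127431 CPM in Q20 female 2, and 98.9 and 727 CPM in Q175 male 4. Its fall is therefore not read as a change of the synthetase mRNA. Rn7s1 had 54.6 ± 32.6 CPM in the 39 libraries of the block of Q20 and 1.04 ± 0.939 in those of the Q175 and WT block.

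Of the 60 oxidative phosphorylation genes 58 fell in Q175 against Q20 (58 also over the list alone), at a median of -0.64, with Ndufa12 at -0.84, Ndufv2 at -0.77 and Ndufb11 at -0.66 (adjusted p = 0.431 with an estimated correlation; fry adjusted p = 0.000325). Progenitor markers rose in 3 of 12 (4 over the list alone): Pdgfra by 0.67, Zfp521 by 0.62 and Fbn1 by 0.82 (adjusted p = 0.938 with an estimated correlation; fry adjusted p = 0.0438). Of 17 heat shock genes 4 fell, also over the list alone: Stip1 by 0.40, Hspe1 by 0.51, Ahsa1 by 0.31 and Dnaja1 by 0.27, all chaperones or their partners, of which Dnaja1 turned positive on FPKM (0.0660 with 0.1 added). In cholesterol biosynthesis Fdps fell by 1.06, Nsdhl by 0.64 and Ebp by 0.50, and 6 of 23 fell over the list alone. Further calls were Fn1 (0.91), Vwf (1.04), the macrophage markers Mrc1 (0.64) and Ccr2 (0.70), the insulin signalling gene Pik3r1 (0.55) and Prdm16 of brown fat (0.54). The interferon-induced Rsad2 (0.66) and the exocrine pancreas genes Cpb1 (4.38) and Cpa1 (4.54) rose, where the pancreas markers summed to 86.1 CPM in Q175 female 2, 208 CPM in Q175 female 3 and at most 11.9 CPM in the other Q175 libraries. Lower were the adipokine Retn (-0.88), Atf4 (-0.48), Acaa2 of fatty acid oxidation (-0.41), and Rnf4 (-0.30), Poln (-1.01) and Haus3 (-0.65) beside Htt. Over the other settings and left-out libraries the call was lost in 22 of 37 for Retn, 21 of 37 for Dnaja1 and 19 of 37 for Fn1. The count was 10453 by voom with quality weights, 6387 on the libraries of these genotypes alone and 1588 at a threshold of 0.01.

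The slope over CAG length was called for 1756 genes, 560 rising and 1196 falling. On FPKM with 0.1 added the balance turned to 1981 and 269, with 61 of the 1756 at the opposite sign. Wdfy3 rose by 0.31 ± 0.05 per 100 repeats (adjusted p = 0.000153), Kmt2a by 0.33 ± 0.05 and the centrosomal gene Cep250 by 0.31 ± 0.05, while Pfdn1 fell by 0.27 ± 0.04 (adjusted p = 2.28e-05) and Rn7s1 by 3.91. Wdfy3 had 61.2 CPM in Q20, 60.6 in Q92, 59.8 in Q140, 93.9 in Q175 and 69.9 in WT, and Cep250 had 37.6, 38.6, 37.9, 56.8 and 57.0 CPM. Of the 60 oxidative phosphorylation genes 46 fell (58 over the list alone; median -0.31; adjusted p = 0.520 with an estimated correlation; fry adjusted p = 0.00558). The progenitor markers Pdgfra (0.36) and Zfp521 (0.37) rose, 4 of 12 over the list alone (adjusted p = 0.520 with an estimated correlation; fry adjusted p = 0.0356). Other members called were Mrc1 (0.34), Ccr2 (0.41), Vwf (0.52), Pik3r1 (0.36), Prdm16 (0.34), Foxj1 (3.19), Stip1 (-0.21), Atf4 (-0.23), Ebp (-0.25) and, beside Htt, Adra2c (0.83), Rnf4 (-0.18) and Poln (-0.56). Over the other settings and left-out libraries the call was lost in 54 of 71 for Adra2c, 45 of 71 for Foxj1 and 34 of 72 for Mrc1. Without Q175, and so within 1 block apart from 1 library, only 1 gene was called, and Wdfy3 (-0.02), Cep250 (-0.00) and Pfdn1 (0.00) reversed sign. The count was 1074 without Q20 female 2, 1155 without Q20 male 3, 1082 without Q20 male 4 and 1030 without Q175 male 3. It was 2762 by DESeq2, 7473 by voom with quality weights, 3089 with 3 surrogate variables, 899 with lane, 682 with length removed, 1124 without the filter, 1162 without the 2 Q140 libraries, 2725 over Q80 to Q175 and 561 at a threshold of 0.01.

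In females alone the slope was called for 505 genes, 131 rising and 374 falling, and on FPKM with 1 added 655 rose and 120 fell. The matrix gene Adamtsl4 rose by 0.73 ± 0.14 (adjusted p = 0.00436), Igdcc3 by 1.42 ± 0.27, the Rac activator Tiam1 by 0.66 ± 0.13, the insulin receptor substrate Irs2 by 0.71 ± 0.14 (adjusted p = 0.00818) and the lipid phosphatase Plpp3 by 0.53. Gucd1 fell by 0.67, the ubiquitin ligase Rnf185 by 0.26 and the cell cycle gene Cdk2ap1 by 0.34. The count was 100, 1 and 152 without Q20 female 1, 2 and 4, 333 without Q111 female 1, 162, 326, 240 and 1324 without Q140 female 1, 2, 3 and 4, and 106, 267, 85 and 135 without Q175 female 1, 2, 3 and 4. It was 1297 by DESeq2, 4853 by voom with quality weights, 775 on FPKM with 1 added, 1674 with 3 surrogate variables and 1798 in female libraries alone. It was 81 with length removed, 239 without small RNAs, 330 on the knock-in libraries alone, 161 without the filter, 169 without the 2 Q140 libraries, 265 with their sexes exchanged, 328 with upper-quartile scaling and 40 at a threshold of 0.01. Q20 female 2, without which 1 gene was left, has a number outside both blocks and had 1438 CPM of Rn7s1.

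In males the slope was called for 75 genes, 14 rising and 61 falling. The actin-responsive coactivator gene Mrtfb rose by 0.48 ± 0.08 (adjusted p = 0.0048), Cep250 by 0.39, Pik3r1, the regulatory subunit of PI3-kinase, by 0.62 ± 0.13 (adjusted p = 0.0229) and the methyltransferase Kmt2d by 0.30. The protease inhibitor Slpi fell by 1.82 ± 0.32, the autophagy gene Gabarap by 0.37 ± 0.07, the lectin Lgals2 by 1.43 and Hcfc1r1 by 0.41. With upper-quartile scaling 21 rose and 32 fell, and on FPKM with 1 added the balance turned to 63 and 17. The count was 223, 28 and 10 without Q20 male 1, 3 and 4, 177 without Q92 male 1, 138 and 133 without Q140 male 1 and 3, and 26, 25, 5 and 17 without Q175 male 1, 2, 3 and 4. It was 424 by DESeq2, 5821 by voom with quality weights, 463 with 3 surrogate variables, 27 with length removed, 15 without small RNAs, 6 with lane, 40 without the filter, 47 without the 2 Q140 libraries and 12 at a threshold of 0.01. The slopes of the sexes differed for 0 genes by edgeR, with 1000 genes at unadjusted p < 0.05, and for 136 by DESeq2, 887 by voom with quality weights, 4 with 3 surrogate variables and 9 without Q20 male 1.

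In Q92 against Q20, 1247 genes were higher and 44 lower. The spindle gene Troap rose by 2.27 ± 0.29 (adjusted p = 1.65e-05; 0.960 ± 0.757 against 0.183 ± 0.0514 CPM), the ubiquitin-conjugating gene Ube2t by 2.44 and the spindle genes Ckap2l and Spag5 by 2.08 and 2.61. Cdkn3 rose by 2.80, Cdca3 by 1.71 and the chromosomal passenger gene Birc5 by 1.65 ± 0.26 (5.10 ± 3.35 against 1.57 ± 0.561 CPM). Of the 20 cell cycle genes 16 rose (19 over the list alone), among them Cenpf by 2.34, Bub1 by 2.58 and Top2a by 1.69, at a median of 1.18 (adjusted p = 0.0187 with an estimated correlation; fry adjusted p = 6.24e-05). Epididymis and testis markers summed to 19971 CPM in Q92 male 1, whose cell cycle sum was the highest (356 CPM), 9563 CPM in male 4 and 241 CPM in male 2, and passed 100 CPM in 1 Q20 male. The use of the list on Q92 was chosen after its count had been seen. In females alone 0 were called over all genes and 14 rose over the list alone (adjusted p = 0.131 with an estimated correlation; fry adjusted p = 0.0577). The summed cell cycle genes of all 4 Q80 females (90.4 to 112 CPM) and of 3 of 4 Q111 females also passed the highest Q20 female (86.9 CPM). The metalloproteinase Mmp9 fell by 1.11 ± 0.22 (adjusted p = 0.00177; 11.1 ± 3.88 against 23.8 ± 6.46 CPM), Litaf by 0.44 ± 0.10, Tiparp by 0.38, the growth factor antagonist Spry2 by 0.41 ± 0.11, Clock by 0.37 ± 0.10 and Pqbp1, which binds polyglutamine, by 0.24.

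Of the 13 skeletal muscle markers 11 rose in Q92 (13 over the list alone; median 7.20; adjusted p = 0.728 with an estimated correlation), with Tnnt3 at 7.88, Myh1 at 8.07, Mylpf at 6.97 and Actn3 at 5.30. With 3 surrogate variables Tnnt3 (-0.19) and Mylpf (-0.25) turned negative. These markers summed to 10801 CPM in Q92 female 1, 3151 CPM in female 2 and 8045 CPM in male 1, and Fabp3 (3.26) and Cpt1b (2.32), which muscle also expresses, rose with them. Of 17 ovary, oviduct and uterus markers 3 rose, also over the list alone: Hsd3b1 by 6.12, Cyp11a1 by 2.10 and Inha by 1.83, all of which the testis also makes. Over the other settings and left-out libraries the call was lost in 21 of 37 for Inha and 20 of 37 for Cyp11a1. Hspa4l (1.11) and, beside Htt, Grk4 (1.37) rose as well, but Hspa4l stood at -0.0789 in the female libraries alone. It stood at -0.113 in an additive design without the libraries high in epididymis and testis markers. The count was 193 without Q92 male 1, 1966 without male 2 and 2594 without male 3, and 0 in females alone and on the libraries of these genotypes alone. It was also 0 in an additive design without the libraries of at least 100 CPM of epididymis and testis markers. It was 2077 by DESeq2, 7173 by voom with quality weights, 2049 on FPKM with 0.1 added, 57 with 3 surrogate variables, 6 with lane, 2897 in the additive design and 555 at a threshold of 0.01.

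**Figure D4:**
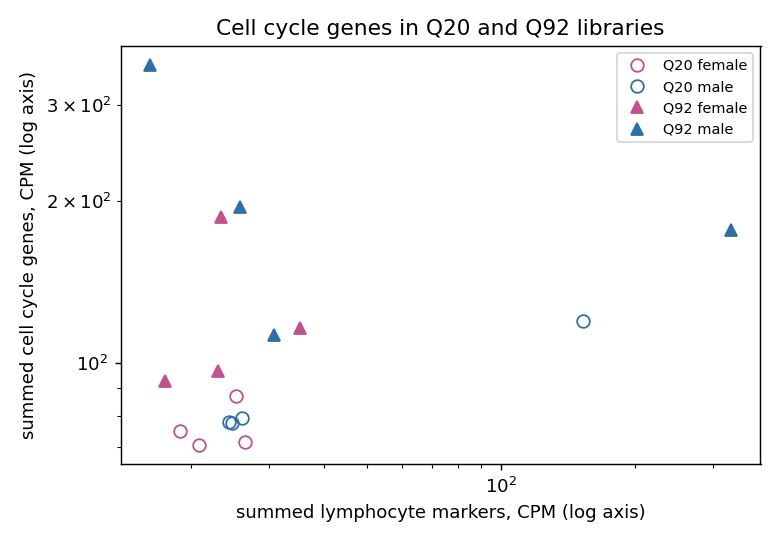
Summed CPM of the cell cycle genes against summed CPM of the lymphocyte markers in each Q20 and Q92 library, log axes, by sex. The 4 Q92 females had 123 ± 43.5 CPM of cell cycle genes and the 4 Q20 females 75.9 ± 7.54 CPM.

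Q20 against WT gave 159 calls, 74 higher and 85 lower. Among the higher genes were the small structural RNAs Rn7s1 at 7.08 ± 0.88 (232 ± 488 against 1.31 ± 1.28 CPM, with 1438 CPM in Q20 female 2), Rn7s2 at 6.62, Rn7sk at 5.25, the RNase P and MRP RNAs Rpph1 at 6.41 and Rmrp at 6.33, Vaultrc5 at 7.25 and Snord17 at 6.27. Lars2, which followed Gm42418 across libraries as above, stood at 3.94. Abhd1, a hydrolase gene, rose by 1.74 ± 0.28 (adjusted p = 0.000153; 12.3 ± 4.95 against 3.70 ± 1.06 CPM) and had 15.1 CPM in Q80 and 9.94 CPM in Q175. The p53 antagonist Mdm4 fell by 0.53 ± 0.08 (adjusted p = 4.16e-05; 109 ± 8.04 against 159 ± 24.2 CPM), Cep250 by 0.60 ± 0.09, and the splicing gene Prpf38b by 0.55. The nuclear matrix genes Safb2 and Safb fell by 0.53 and 0.44, the helicase Ddx17 by 0.42 ± 0.07, Kmt2d by 0.51 ± 0.08 and Akap8 by 0.41. Among list members, the insulin signalling gene Pik3r1 fell by 0.64 (adjusted p = 0.0414) and Ndufb2 of complex I rose by 0.45 (adjusted p = 0.0359). Over the other settings and left-out libraries the call was lost in 21 of 36 for Pik3r1 and 18 of 36 for Ndufb2. The count was 70, 92, 358, 89 and 100 without WT female 1, female 3, male 1, male 3 and male 4, and 94, 101 and 81 without Q20 female 2, female 4 and male 4. It was 560 by DESeq2, 2019 by voom with quality weights, 105 on FPKM with 1 added and 461 with 3 surrogate variables. An additive design without the libraries high in epididymis and testis markers gave 543. The count was 0 in females alone, 86 with length removed, 90 without small RNAs, 10 on the libraries of these genotypes alone and 58 at a threshold of 0.01.

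Q80, Q111 and Q140 each had 0 genes called against Q20 by edgeR. They had 1681, 1466 and 2177 genes at unadjusted p < 0.05 and smallest adjusted p of 0.328, 0.272 and 0.164. DESeq2 called 167, 158 and 504 genes and voom with quality weights 7, 404 and 0, and the additive design called 7 in Q111 and 278 in Q140. Without Q20 male 1, Q80 had 1 gene. In Q140 over the list alone, the clock genes Arntl (1.29) and Npas2 (1.41), the thermogenesis members Slc27a2 (5.78), a fatty acid transporter, and Gk (2.07), glycerol kinase, 6 muscle markers, Foxj1 (6.52) and Adra2c (1.56) beside Htt had adjusted p under 0.05. The doubtful sex labels bear on these values, since Xist stood at 4.43 and Ddx3y at 4.28 in Q140 against Q20 (neither called), and Arntl was 2.16 higher in males. The 22 adipocyte identity genes were all negative in Q140, at a median of -0.21, with no member called (adjusted p = 0.858 with an estimated correlation). In the female libraries alone, taken without Q140 female 1, 8 of the 22 were positive and the median was -0.09. Of the 4 Q140 males 3 held at least 100 CPM of epididymis and testis markers.

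Q140 against Q20 and Q175 against WT share no libraries. Their log2 fold changes had r = 0.18 and rho = 0.16 across genes, and 54.7% had the same sign, over genes that are not independent replicates. This r turned to -0.0575 with the lane code as a factor, -0.141 with 3 surrogate variables and -0.055 without Q140 male 1. Its jackknife SE over libraries was 0.447, so its sign is open. Among the 2204 genes called in Q175 against WT 46.2% had the same sign. At unadjusted p < 0.05, 101 genes were higher in both where 187 would be expected of unrelated lists, and 50 were lower in both against 54.2 expected. For the slope over Q20 to Q140 against Q175 to WT, 85 were higher in both against 120 expected and 84 lower in both against 64.4.

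**Figure D5:**
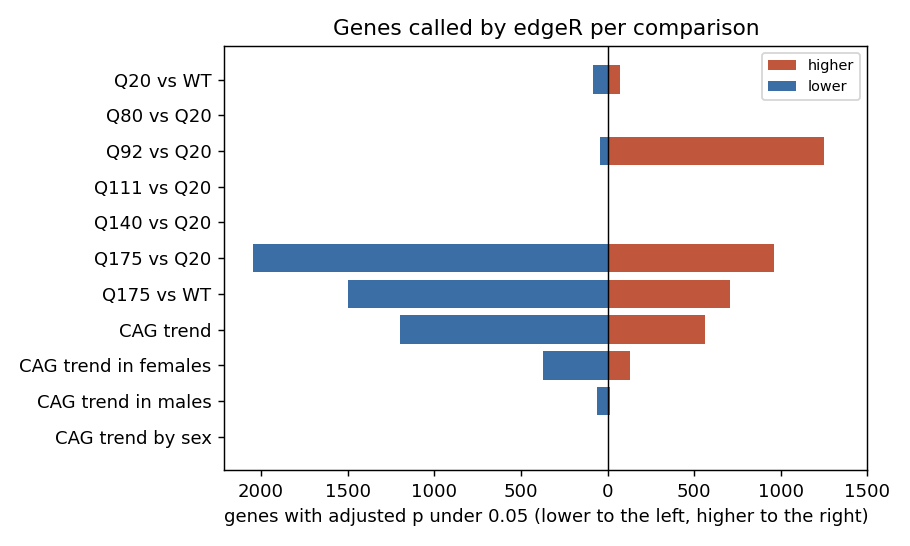
Number of genes called higher and lower in each genotype and trend comparison. Q175 against Q20 had 3006, Q175 against WT 2204 and Q92 against Q20 1291, and Q80, Q111 and Q140 had 0.

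Males and females differed in 9770 genes, 5898 higher in males and 3872 lower. In an additive design without the libraries high in epididymis and testis markers, which are 15 of 28 male libraries, 3508 were higher and 3177 lower. There 4623 of 9052 measured calls were kept and 826 had the opposite sign, with design and libraries changed together. With the length trend removed 4452 were higher and 5400 lower, and on FPKM with 0.1 added 9051 and 2173. Beside the Y-linked Kdm5d (7.03), Ddx3y (9.26 ± 0.67), Eif2s3y (9.84) and Uty (9.01), the estrogen sulfotransferase Sult1e1 was higher by 8.92 ± 0.66 (74.1 ± 34.6 against 3.99 ± 20.3 CPM), and complement C7 by 5.30 ± 0.42. Also higher were the clock gene Arntl by 2.16 ± 0.18 (9.54 against 2.45 CPM), Cyp1b1, which oxidizes steroids, by 1.69 ± 0.13 and the collagen gene Col6a5 by 3.75. Lower were Xist (-8.51 ± 0.70), the homeobox gene Hoxc10 (-4.60 ± 0.37), the urinary proteins Mup10 (-6.82 ± 0.56; 7.89 against 242 CPM) and Mup18 (-6.94), the steroid reductase Akr1c14 (-2.96 ± 0.26) and Mtss1 (-0.86). Unless a setting is named, values by sex include the 2 Q140 libraries of contradicting sex, as labelled. Each fold change is a mean over genotypes, so it need not match the ratio of the mean CPM, as for Sult1e1.

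Among the metabolic lists, lower in males were 54 of 60 oxidative phosphorylation genes (56 over the list alone; Cox7b -0.46), 15 of 22 lipogenesis genes (16 over the list alone; Elovl6 -2.43, Acss2 -1.41, Gpam -1.10), 12 of 23 cholesterol genes, and 10 of 21 fatty acid oxidation genes (12 over the list alone). Also lower were 9 of 16 thermogenesis genes (9 also over the list alone, with 3 higher; Ucp1 -3.62, Elovl3 -3.35, Dio2 -1.80), 5 of 22 adipocyte identity genes (5 also over the list alone; Retn -0.71, Rbp4 -0.68, Slc2a4 -0.56) and 7 of 16 insulin signalling genes (Irs1 -0.86). Higher were 3 cholesterol genes, 1 of each of the lipogenesis, oxidation and adipocyte identity lists (Aqp7 at 0.34 in the last), 2 thermogenesis genes and 3 insulin signalling genes, with the adaptor Grb14 at 2.02. With an estimated correlation, adjusted p = 0.566 for oxidative phosphorylation and cholesterol, adjusted p = 0.4995 for lipogenesis, adjusted p = 0.708 for fatty acid oxidation, adjusted p = 0.578 for thermogenesis and adjusted p = 0.774 for adipocyte identity. The circadian list kept its call (adjusted p = 0.0339 with an estimated correlation), with 12 of 17 lower, as Dbp (-1.43) and Nr1d2 (-0.68), and 3 higher, as Clock (0.59) beside Arntl.

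Higher in males were 16 of 20 lymphocyte markers (18 over the list alone; adjusted p = 0.708 with an estimated correlation) and 7 of 7 erythroid genes (7 also over the list alone; Alas2 1.25, Hbb-bt 1.12; adjusted p = 0.4995 with an estimated correlation). Of 21 epididymis and testis markers 15 were higher and 1 lower (Crisp1 10.84, Prm2 7.84; adjusted p = 0.708 with an estimated correlation), and of 19 macrophage markers 6 and 1 (Gpnmb 1.86, Itgax 1.33). Higher and lower were 10 and 3 of 17 ovary, oviduct and uterus markers (12 and 3 over the list alone), 8 and 1 of 20 cell cycle genes, 10 and 4 of 18 unfolded protein response genes, 4 and 3 of 17 heat shock genes and 4 and 3 of the 18 genes beside Htt. None were lower of 15 immediate early genes (2 higher), 12 endothelial markers (2 higher), 7 mammary markers (3 higher) and 12 exocrine pancreas markers (1 higher, 0 over the list alone). The mammary markers summed to 37.6 CPM in Q20 male 1 and to at most 0.577 CPM in Q20 male 2, 3 and 4. Q80 male 4, not high in epididymis and testis markers, had 15.1 CPM. Tract tissue may have given a part of the mammary calls as well.

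Lower in males were 11 of 13 muscle markers (Myh2 -4.60; adjusted p = 0.809 with an estimated correlation), 12 of 24 interferon genes (13 over the list alone; Ifit3 -0.61) and 10 of 24 matrix genes (Lum -1.80, Postn -1.59), with 1 higher in each of the last lists. The muscle markers summed to 1314 to 10801 CPM in 6 female libraries, Q92 female 1 and 2, Q80 female 2, Q111 female 2, Q140 female 2 and Q175 female 4, and to at most 562 CPM in the other females. The interferon and matrix lists each had adjusted p = 0.578 with an estimated correlation. Of 8 Schwann cell markers 5 were lower and 2 higher (5 and 3 over the list alone; adjusted p = 0.4995 with an estimated correlation), of 9 mesothelial markers 4 and 2 (5 and 2 over the list alone) and of 12 progenitor markers 3 and 2, where on FPKM with 0.1 added none were lower and 3 higher. For the lists between males and females where no other count is given, adjusting over the list alone left the counts as they were. Htt stood at 0.07 (adjusted p = 0.114).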

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

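The test of exchanged sex labels was written down before its result was seen. The test of mixed RNA, both tests of tissue in Q92 and all counts over other splits were chosen only after the result was seen. In the splits the libraries of the genotypes compared were regrouped within each sex in 50 ways, the real one included, and for males against females the sexes were regrouped within each genotype.

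In 13 groups of 4 libraries, 12 measures were tested for 1 library apart from the other 3 by Dixon's ratio, in 156 tests, and chance flags about 1 in 20 groups. In total count, Q80 female 2 stood apart at 39991600, below 43572900 and more in the others. In Htt it was Q140 male 3 at 39.4 CPM against 50.1 to 50.8, and in Rn7s1 Q20 female 2, the library with a number outside both blocks, at 1438 CPM against 38.3 to 53.0.

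In Xist, WT male 3 stood apart at 27.6 CPM and Q111 male 1 at 15.3 CPM, against at most 0.579 and 0.487 CPM in the other males, and Q111 female 4 at 728 CPM. The Q140 pair had Xist at 0.515 CPM in female 1 and 711.8 CPM in male 4. In Ddx3y, Q140 female 1 had 76.6 CPM, Q111 male 3 had 121 CPM and Q92 female 2 had 0.0240 CPM beside females with none.

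Epididymis and testis markers set apart Q20 male 1 (6787 CPM), Q80 male 1 (19072 CPM), Q111 male 1 (1420 CPM), Q140 male 1 (27997 CPM) and WT male 2 (49.3 CPM). Among females they set apart Q140 female 1 (19.3 CPM) and Q175 female 1 (5.24 CPM). Skeletal muscle markers did so for Q80 female 2 (5524 CPM), Q92 male 1 (8045 CPM), Q111 female 2 (1725 CPM), Q140 female 2 (1507 CPM), Q140 male 2 (426 CPM) and Q175 female 4 (1314 CPM). Exocrine pancreas markers were apart in WT male 3 (598 CPM), and lymphocyte markers in Q20 male 1 (153 CPM) and Q92 male 2 (331 CPM).

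The sex genes of the Q140 pair may reflect exchanged labels or RNA of both sexes in a tube. Mixing is argued against by Xist at 0.515 CPM in female 1, where the lowest other female library had 314 CPM. In male 4, Ddx3y, Kdm5d, Eif2s3y and Uty summed to 0.188 CPM, where the lowest other male library had 138 CPM. Of 9945 autosomal genes called between the sexes without the pair, 70.5% in female 1 and 84.7% in male 4 lay nearer the other sex, against at most 63.5% in any other library. The other libraries set these genes and the means of the sexes, so their shares are not a like comparison. In 8 of them most of these genes also lay nearer the other sex. An exchange of labels, of animals or of tubes remains open, and so does a wrong sexing of each animal on its own. The 2 libraries have consecutive numbers, 372706 and 372707, and the same lane code, which does not decide among these. With the sexes exchanged the slope in females had 265 genes against 505.

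The many genes called in Q92 may come from reproductive tract tissue in male libraries, from lymphoid tissue or from dividing cells of the fat itself. For most called genes such tissue is not argued against: the higher genes had a median of 2.20 in both sexes and 0.295 in the 996 measured in female libraries. For the summed cell cycle genes in females both tissues are argued against. All 4 Q92 females had more than every Q20 female (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give), as all 4 Q80 females also did. Only 1 Q92 female passed every Q20 female in the lymphocyte markers. Tests in females cannot clear these tissues from the calls of both sexes. Q92 male 1 had 19971 CPM of epididymis and testis markers and 356 CPM of cell cycle genes. Q92 male 2 had 331 CPM of lymphocyte markers and 176 CPM of cell cycle genes. Of 50 splits, 2 had as many calls as the real 1295 of the refit, with 1318 in the highest other, so a regrouping can give as many genes, which points to structure of the samples. Muscle tissue in 3 Q92 libraries, housing and the length of the repeat remain open.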

How the results depend on the processing

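Counts of called genes under other settings are given for Q20 against WT, Q80, Q92, Q111, Q140 and Q175 against Q20, Q175 against WT, the slope over CAG length, the slope in females, in males and by sex, and male against female. Settings that are not named for a comparison left its count within 1.5 times. Where a value moved, the cause was not tested unless stated.

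DESeq2 called 560 genes in Q20 against WT, 167 in Q80, 2077 in Q92, 158 in Q111, 504 in Q140, 2762 for the slope, 1297 in females, 424 in males and 136 by sex, and it called Htt in Q111 (-0.29) and Q140 (-0.35). Voom with quality weights called 2019 in Q20 against WT, 7 in Q80, 7173 in Q92, 404 in Q111, 10453 in Q175 against Q20, 8416 in Q175 against WT, 7473 for the slope, 4853 in females, 5821 in males and 887 by sex, with Htt called in Q111 (-0.30) and in Q175 against WT (-0.17). The additive design called 2897 in Q92, 7 in Q111 and 278 in Q140, with Htt called in Q140 (-0.37). At a threshold of 0.01 the counts were 58 in Q20 against WT, 555 in Q92, 1588 in Q175 against Q20, 808 in Q175 against WT, 561 for the slope, 40 in females and 12 in males, and Htt in Q92 (-0.25) was lost.

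On log2 FPKM with 1 added the counts were 105 in Q20 against WT, 2088 in Q92 and 775 for the slope in females. The Htt call in Q92 was lost (-0.0944), Htt turned positive in Q175 against Q20 (0.20), in Q175 against WT (0.0138), for the slope (0.0554), in females (0.0493) and in males (0.0615), and it was called in males against females (0.19). With 0.1 added Q92 had 2049, its Htt call was lost (-0.12), and Htt was positive in Q175 against Q20 (0.24), in Q175 against WT (0.0170), for the slope (0.0630), in females (0.0569) and in males (0.0691), and called in males against females (0.23). Dnaja1 in Q175 against Q20 turned to 0.0650 and 0.0660 with 1 and 0.1 added.

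With 3 surrogate variables the counts were 461 in Q20 against WT, 57 in Q92, 3089 for the slope, 1674 in females, 463 in males and 4 by sex. The Htt call in Q92 was lost (-0.29), the correlation between the comparisons with no shared library was -0.141, and Mal in males against females (-0.0780) and Tnnt3 (-0.19) and Mylpf (-0.25) in Q92 turned negative. With the lane code as a factor they were 6 in Q92, 417 in Q175 against WT, 899 for the slope and 6 in males, with the Htt call in Q92 lost (-0.19) and the correlation at -0.0575. With upper-quartile scaling 328 genes had a slope in females. RLE scaling and a mean of 1 CPM each ended the Htt call in Q92 (-0.22 and -0.22, adjusted p 0.0598 and 0.0540). Without the filter there were 1434 in Q175 against WT, 1124 for the slope, 161 in females and 40 in males, and Htt in Q175 against Q20 stood at 0.000583.

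On the libraries of the genotypes compared alone the counts were 10 in Q20 against WT, 0 in Q92, 6387 in Q175 against Q20, 6002 in Q175 against WT and 330 for the slope in females, with the Htt call in Q92 lost (-0.23). The slope over Q20 to Q140 was called for 1 gene, Htt (-0.32), with Wdfy3 (-0.0200), Cep250 (-0.000578) and Herc2 (-0.0151) negative and Pfdn1 (0.00412) positive, and the slope over Q80 to Q175 was called for 2725 genes, with Htt at 0.10. The slope over ranks stayed within 1.5 times.

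Of the alternatives chosen after seeing the data, leaving out the reproductive tract libraries and the 2 Q140 libraries also used an additive design, so design and libraries changed together. That fit gave 543 in Q20 against WT and 0 in Q92, with the Htt call in Q92 lost (-0.30). Htt in Q175 against Q20 stood at 0.0106, and the comparisons with no shared library had a correlation of -0.00349. In males against females Mal stood at -0.54, Cdc20 at -0.0100, Rrm2 at -0.10 and Ccnb2 at -0.0148, and in Q92 Hspa4l at -0.11. Female libraries alone, without Q140 female 1, gave 0 in Q20 against WT, 0 in Q92, 1322 in Q175 against WT and 1798 for the slope in females. The Htt call in Q92 was lost there (-0.36) and Hspa4l in Q92 stood at -0.0789. Removing the trend over length gave 86 in Q20 against WT, 682 for the slope, 81 in females and 27 in males, with Htt called in Q175 against WT (-0.38) and for the slope (-0.18), and at -0.0232 in males against females. Without small RNA genes there were 90 in Q20 against WT, 239 in females and 15 in males. Without the 2 Q140 libraries the slope had 1162, females 169 and males 47, and with their sexes exchanged females had 265.

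The replicate numbers of the titles do not pair the libraries: their deviations from the group mean correlated at 0.0312 on average, and 89 of 351 pairs passed 0.1. With the replicate number as a block (replicate block) the counts were 141, 0, 1192, 0, 0, 3116, 2353, 1805, 570, 60, 0 and 9659 in the order above.

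Leaving out each library in turn gave 70 to 358 in Q20 against WT, 0 to 1 in Q80, 193 to 2594 in Q92, 0 to 0 in Q111 and Q140, 2238 to 3516 in Q175 against Q20, 1073 to 2790 in Q175 against WT, 1030 to 2447 for the slope, 1 to 1324 in females, 5 to 223 in males, 0 to 9 by sex and 9042 to 10300 for sex. For Htt it gave -0.23 to -0.10 in Q20 against WT, -0.16 to -0.10 in Q80, -0.27 to -0.21 in Q92, -0.33 to -0.26 in Q111, -0.39 to -0.32 in Q140, -0.0462 to 0.0101 in Q175 against Q20, -0.25 to -0.11 in Q175 against WT, -0.10 to -0.06 for the slope, -0.14 to -0.07 in females, -0.07 to -0.03 in males, 0.02 to 0.09 by sex and 0.0493 to 0.10 for sex. Htt in Q92 was not called without Q20 female 3, male 2 or male 3 or Q92 female 1, female 3 or male 1. In Q175 against Q20 it was positive without Q20 female 3 (0.0101) or Q175 male 1 (0.00988), and it was called in Q175 against WT without WT female 1 and for sex without WT female 2. The correlation of the comparisons with no shared library ran from -0.055 (without Q140 male 1) to 0.41 (without Q20 male 1), with -0.00347 without Q140 female 1. Its SE, a jackknife over 31 libraries, was 0.447, so its sign is open.

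Camera with an estimated correlation called 0 lists in Q20 against WT, Q140, both Q175 comparisons and the slope, and 1 in males against females. Fry called 0, 0, 2, 2 and 2 in Q20 against WT, Q140, Q175 against Q20, Q175 against WT and the slope. For 375 named gene results, 19912 values were computed, of which 18621 kept call and sign, 1276 lost the call and 15 reversed. Without a library, 11874 of 12369 kept both and 495 lost the call. Settings of 1 sex gave no values for the other sex or for the difference between sexes, and the fit without reproductive tract libraries none for slopes within a sex, since no Q175 male was left. With simulated changes, 75.8% of 4-fold, 40.3% of 2-fold and 26.9% of 1.5-fold changes were recovered in Q175 against WT, so changes of each of these sizes are missed. In that run 6 unchanged genes were called. The simulation held no block, lane or foreign tissue, so recovery in the real libraries may differ. The read depth of the libraries limits genes of low count, which was not tested here.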

Other observations

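Beyond the lists, members of some families taken by symbol after seeing the data were called in Q175 against WT. Of 78 mitochondrial ribosomal protein genes 58 fell (71 over the list alone; median -0.38; adjusted p = 0.0722 with an estimated correlation), and of 19 ATP synthase genes, which make ATP from the proton gradient, 11 fell (17 over the list alone; median -0.48; adjusted p = 0.0722 with an estimated correlation). Of 44 proteasome genes, whose products degrade ubiquitinated proteins, 21 fell and 1 rose (27 and 1 over the list alone; median -0.30; adjusted p = 0.0804 with an estimated correlation). Of 25 genes of Sm and Lsm proteins, which build the spliceosome, 14 fell (19 over the list alone; median -0.34; adjusted p = 0.0390 with an estimated correlation), and of 87 cytosolic ribosomal protein genes 17 (36 over the list alone; adjusted p = 0.213 with an estimated correlation). Collagens rose in 2 of 43 genes (1 over the list alone) at a median of 0.55 (adjusted p = 0.0722 with an estimated correlation). Against 10000 random lists matched on length and level, the cytosolic ribosomal median (-0.26) lay within their range (lowest -0.35, 1195 as extreme), and so did the Sm and Lsm median (lowest -0.37, 11 as extreme). The medians of the mitochondrial ribosome (lowest -0.22), the proteasome (lowest -0.29) and the collagens (highest 0.36) lay outside, and so did that of the ATP synthase (lowest -0.46), though 2 lists were as extreme. Random lists leave out the correlation among the members of a family. The directions of the families that fell and of the collagens held with RLE and upper-quartile scaling, with 57 and 51 mitochondrial ribosomal genes lower. In the female libraries alone 3 of 25 Sm and Lsm genes (11 over the list alone) and 1 of 85 cytosolic ribosomal genes (0 over the list alone) fell, and the Sm and Lsm call was lost (adjusted p = 0.131 with an estimated correlation). Of 390 Zfp zinc finger genes 15 rose and 15 fell in Q175 against WT (9 and 8 over the list alone; adjusted p = 0.587 with an estimated correlation). In Q140 against Q20 no member of these families was called.

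Of 17 major urinary protein genes, whose products carry pheromones, 16 were lower in males than in females (16 over the list alone; median -5.35; adjusted p = 0.0144 with an estimated correlation). Collagens were called in both directions, 17 higher and 9 lower of 43 (18 and 10 over the list alone), and 48 of 78 mitochondrial ribosomal genes were lower in males (53 over the list alone; adjusted p = 0.518 with an estimated correlation).

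For Q175, the test of the library number block on all called genes was written down before its result was seen. The tests of reproductive tract tissue, of transcript length and of small RNAs, and all counts over other splits, were chosen only after the result was seen.

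The genes called in Q175 may come from reproductive tract tissue in its males, from a trend over transcript length such as differences in RNA quality or library making give, from the block of library numbers, or from the repeat itself. Tract tissue as the sole source is argued against by the 1322 genes called in females alone, 911 of them among the 2204 of both sexes. The epididymal genes Crisp1 and Gpx5 were among the calls. All Q175 males and no WT male passed 100 CPM of epididymis and testis markers, so tract tissue may have given a part. Length as the sole source is argued against by the 1414 of 2204 calls that remained once its trend was removed, and by the oxidative phosphorylation median of -0.56 against a lowest median of -0.31 in 10000 random lists matched on length and level. Those lists show that other genes of like length and level fell less. They leave out the correlation among the list's members and do not test other differences in RNA quality. The block as the whole source of the genes called in Q175 against Q20 is argued against, since the median difference of WT from Q20 was 26.4% of the called one, and 80.3% of the genes went the same way, which the Q20 libraries shared by both differences favour, while for the small RNAs that median share reached 85.9%, so their fall fits the block. A partial share of tract tissue, length, block and lane, housing apart from WT and an effect of the repeat remain open. All WT females carried lane code 6, and the Q175 females codes 5, 6, 7 and 8. The count in Q175 against WT fell with the lane code as a factor, as given above.

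Counts over splits come from refits, whose real counts differ slightly from those of the full fit. Among 50 splits of the same libraries, only the real grouping gave as many calls (1 of 50) in Q20 against WT (159, highest other 12), Q175 against Q20 (3003, highest other 2), Q175 against WT (2204, highest other 17), the slope in females (504, highest other 114) and males against females (9774, highest other 990), so chance alone is argued against there, at the smallest share that 50 splits can give. Without Q20 female 2, whose number lies outside both blocks, the slope in females had 1 gene. The splits do not test this dependence on 1 library. For the slope 2 of 50 splits gave as many as 1756, with 2574 in the highest other, so 1 other split passed it. In males 14 of 50 gave as many as 75, with 8805 in the highest other, so chance cannot be excluded and the high count points to structure of the samples. With 0 real calls all 50 of 50 gave as many in Q80 (highest other 0), Q111 (highest other 0), Q140 (highest other 948) and by sex (highest other 2100), and the last counts also point to structure of the samples.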
